A study of Mus musculus with 2 samples.

How the data were processed

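RNA from skin keratinocytes of mice was measured on 2 Illumina bead arrays, 1 for a control group and 1 for a group labelled as vitamin D receptor (VDR) knockout. Per the labels' protocols, the mice were 3 months old and kept on a diet low in calcium, excised skin was treated with 0.25% trypsin, the epidermis was taken off the dermis, and keratinocytes were isolated from the epidermis. Per the design text, the RNA on each array came from the skin of 3 mice, so that each array stood for a pool and each group held 1 array. Groups were taken from the genotype labels. Per the file headers, both columns carry the same chip number with different position letters, so the arrays were read as positions on a shared chip. The type of array was not given in the sources used here.

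The deposited non-normalized table holds the average bead intensity of each of 25697 probes on a linear scale, per the file headers, as written by GenomeStudio 2011.1 per the submitters' processing notes. All intensities lay above 100, so no background had been subtracted. The deposited normalized intensities have the same sorted values on both arrays to within 0.3 units, and they keep the order of the probes. Their common distribution lay a median of 1.066 times above the mean of the sorted non-normalized intensities of these 2 arrays, which leaves open whether other arrays entered the normalization, whose method was not given in the sources used here. A further deposited value table was identical to the normalized intensities (medians 169.5 for control and 169.4 for knockout, linear scale, not centred).

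Each table also has a deposited detection p-value per probe and array, per the file headers. In both tables these p-values did not follow the rows of the intensities: Spearman's rho across probes was -0.0053 on the control array and -0.0073 on the other. As filed, 40.3% of 1149 probes for olfactory receptors had a detection p under 0.05 on the control array. The intensities did follow the annotation, with a median of 7617 for 90 probes of ribosomal protein genes against 140.1 for the olfactory receptor probes. The number of probes with p under 0.05 on both arrays was 11238 as filed and 11230 when the p-values of each array were reassigned by the rank of the intensity. The reassigned p-values were therefore used, the smallest going to the brightest probe and tied probes taking the larger p. With them, 2.1% of the olfactory receptor probes and 76.7% of the ribosomal probes were detected. This step was chosen after the data were seen and replaces the p-values as filed everywhere.

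From the non-normalized intensities, the background was removed with the normexp model of limma 3.58.1 (R 4.3.3), fitted through the detection p-values with an offset of 16, followed by log2 and quantile normalization. The fitted background had a mean of 143.2 and an SD of 10.3 on the control array, and a mean of 140.9 and an SD of 10.1 on the other. A probe was kept when its detection p was under 0.05 on at least 1 array, and each gene was represented by its probe with the highest mean signal. A gene detected on 1 array alone has only a bound on the other, where it was not well above background. The bound sets the bright value against the higher of the dim value and the lowest normalized value among detected probes of that array, and it is written as "at least N-fold". It holds only under this background model, since the deposited normalized values, which keep the background, gave smaller folds for every named bound of at least 2-fold. For 22 genes another, dimmer probe was detected on the array where the chosen probe was not, and 2 of these (Slc7a7 and Tpd52l1) are among the genes counted at 2-fold. Removing the background widens folds at low signal, so that folds of dim genes exceed the ratio of their printed signals.

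Symbols of the array design were updated through the gene table of the mouse assembly GRCm38.p6, which was used for names and gene neighbourhood only. In all, 25376 probes matched, 16938 by Entrez number, 7420 by RefSeq accession, 465 by symbol and 553 by synonym, and 321 kept the symbol of the file. This gave 17871 genes.

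With 1 array per group there is no spread between replicates, so no test was made and no p-value is given for any difference. Genes were counted when the normalized difference was at least 2-fold. For 36 gene lists, fixed from the tissue and the question, the median difference over detected members was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and its percentile describes these 2 arrays alone. Lists with fewer than 4 detected members have values only. The genes named were Vdr, then the 10 largest differences in each direction among named genes detected on both arrays and at least 2-fold under the main setting, without background correction and in the deposited normalized values, then the 5 largest bounds in each direction, and the 4 members of each list with the largest difference. In a list with no member at 2-fold, the 2 brightest members were taken instead. A gene of the cholesterol synthesis list that this rule names is not reported here. The lists, this rule, the threshold and the alternatives were fixed before the data were examined. In the hair stem cell list, Tcf3 was written as an older name of Tcf7l1 and was not counted again.

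The alternatives were the deposited normalized values, no background correction, an offset of 50, scaling to the median in place of quantile normalization, a detection p under 0.01, detection on both arrays, no detection filter, the mean of all detected probes of a gene, and thresholds of 1.5-fold and 3-fold. The normalization was tested on simulated data in which 200 probes were changed, 50 for each size. They were drawn from the probes with the lowest detection p on both arrays. At 4-fold (log2 of 2) 100% of the raised and 96% of the lowered probes came out at 2-fold or more, and at a log2 of 1.5 the shares were 100% and 96%. Among 11507 simulated unchanged probes 0% passed, although the simulated noise was smaller than the spread seen between these arrays. The percentile step was tested on 200 random lists of 15 genes, of which 3.0% fell outside the central 95%, and 100% did after a shift of 0.5 was added. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.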

Results

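Gene expression was measured in epidermal keratinocytes from mice with floxed Vdr alleles (control) and from littermates that also carried a Cre recombinase driven by the Krt14 promoter (labelled knockout). Krt14 encodes a keratin of basal epidermal cells and of the outer cells of the hair follicle, so the recombinase acts in these cells and their descendants. Each group was represented by 1 array that held RNA pooled from 3 mice. The series title places the comparison within a study of VDR in epidermal stem cells and in wound repair, although neither sample label mentions a wound. In total, 11994 of the 25697 probes (46.7%) were detected on the control array and 12147 (47.3%) on the array labelled knockout, with median signals of 158.3 and 155.4. Across probes detected on both arrays the signals correlated with a Spearman's rho of 0.982, where probes are not independent replicates. The number of arrays limits the precision, and the difference has no replicate check.

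Vdr, the nuclear receptor for the hormonal form of vitamin D and the targeted gene, was not lower on the array labelled knockout. Its brightest probe had a signal of 2468 on the control array and 2667 on the array labelled knockout, a log2 difference of 0.17 (1.12-fold). The other probes gave 1514 against 1692 (0.23) and 237.8 against 304.7 (0.77). The labels do not say which exon was removed and the probe positions were not analysed here. A probe outside the deleted part would check nothing, so Vdr gave no support for the genotype label, and every direction below rests on that label as given.

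Among sex-linked transcripts, Xist, which is transcribed from the inactive X chromosome of females, was 2.22-fold and 2.03-fold higher by its probes on the array labelled knockout. The Y-linked genes Ddx3y and Kdm5d were 7.87-fold and 2.36-fold lower there, and 3.58-fold and 1.44-fold lower in the deposited normalized values. Uty was close to background on the control array (164.2) and not well above background on the other (155.1). The list of sex-linked transcripts had 4 detected members, with a median of -0.72 (-0.65 with bounds, percentile 0.2), 1 at 2-fold higher and 2 at 2-fold lower. Xist and the Y-linked genes of this list went opposite ways, so its median and percentile depend on how many of each were detected. These sex-linked differences stand beside every group described below.

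**Figure D1:**
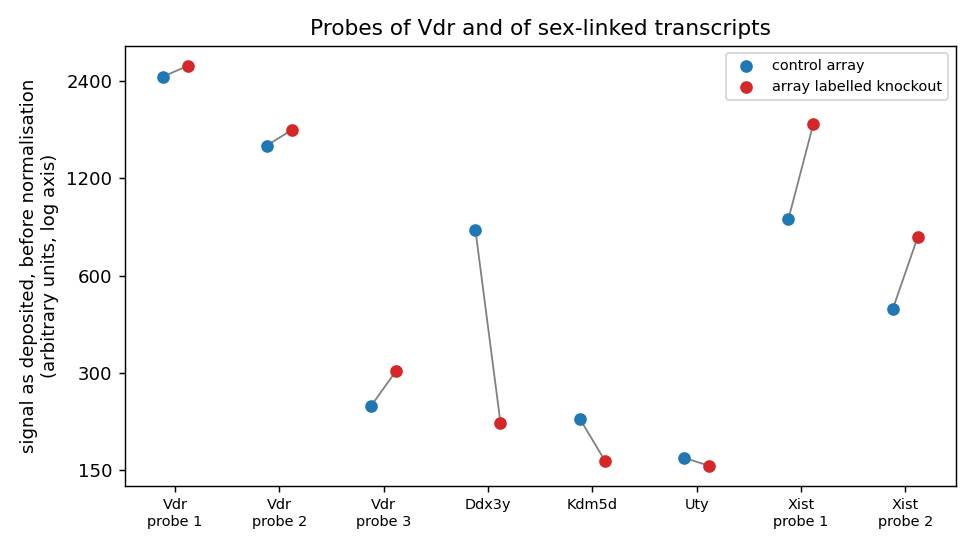
Signal per probe before normalisation (arbitrary units, log axis) for Vdr and for the detected probes of sex-linked transcripts, with 1 point per array (blue, control; red, labelled knockout) and a line joining the same probe. All 3 Vdr probes and both Xist probes lay higher on the array labelled knockout, whereas Ddx3y lay at 828.5 on the control array against 210.3 and Kdm5d at 216.9 against 161.0.

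Several genes for proteins of the outermost epidermis and of inflamed skin were higher on the array labelled knockout, and several genes of the hair shaft, inner root sheath and pigment cells were lower. The calprotectin subunit gene S100a8 was 8.88-fold higher (signal 321.9 against 1782), and the stefin A protease inhibitor genes Stfa3 and Stfa1 were 8.36-fold and 6.42-fold higher. Dct, the gene of an enzyme of melanin synthesis, was 10.3-fold lower (533.5 against 162.3), and Krt71, a keratin gene of the inner root sheath of the hair, was 7.22-fold lower (390.3 against 159.5). Removing the background widens these folds, which in the deposited normalized values were 5.03 for S100a8, 3.12 for Stfa3, 5.62 for Stfa1, 3.40 for Dct and 2.64 for Krt71. Most genes differed little, with a median absolute log2 difference of 0.17 over the 8393 genes detected on both arrays.

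In total, 228 of 9547 detected genes differed by at least 2-fold, of which 122 were higher and 106 lower on the array labelled knockout. Of these, 102 and 72 were detected on both arrays, and 20 and 34 were bounds. The remaining 97.6% lay within 2-fold. Some genes were at least 2-fold apart in the main setting, without background correction and in the deposited normalized values, and the genes named next are limited to these and to detection on both arrays. Under that limit the 10 largest differences upward also included the simple-epithelium keratin Krt7 (5.77-fold), the chitinase-like protein gene Chil1 (5.72-fold), Mgarp (5.53-fold), the late cornified envelope genes Lce1d (5.49-fold) and Lce1i (4.22-fold), the peptide hormone gene Pyy (4.31-fold) and the small proline-rich protein gene Sprr4 (3.77-fold). Under the same limit the 10 largest downward also included the Ras exchange factor Rasgrf1 (4.95-fold), Wfdc3 (4.86-fold), Shisa2 (4.08-fold), the G protein subunit Gng13 (3.90-fold), the transcription factor Tbx1 (3.87-fold), the Wnt antagonist Nkd2 (3.77-fold) and Nrep (3.70-fold). In the deposited normalized values the upward folds were 2.5 for Krt7, 4.3 for Chil1, 2.32 for Mgarp, 3.85 for Lce1d and 2.32 for Lce1i. Pyy and Sprr4 were at 2.81 and 3.29. The downward folds there were 2.2 for Rasgrf1, 2.57 for Wfdc3, 2.47 for Shisa2, 2.69 for Gng13 and 2.34 for Tbx1. Nkd2 and Nrep were at 2.17 and 2.43.

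Several genes were not well above background on 1 of the arrays. Their bounds hold only under the background model used here, and folds in the deposited normalized values, which keep the background, were smaller. The protease inhibitor gene Serpinb3a was at least 10.6-fold higher on the array labelled knockout (157.1 against 500.6), although it has near-identical neighbours that its probe may also bind. Fhl2 was at least 6.51-fold higher (163.1 against 355.1), the pantetheinase gene Vnn3 at least 6.37-fold (146.9 against 351.0), Ugt3a2 at least 4.21-fold (156.1 against 275.2) and Scgb1b27 at least 3.74-fold (142.8 against 258.3). In the other direction, the growth factor gene Gdf10 was at least 5.49-fold lower (326.5 against 144.1), the claudin gene Cldn10 at least 4.17-fold (277.9 against 148.1) and Fam171b at least 4.10-fold (275.3 against 156.1). Anxa3 was at least 3.61-fold lower (257.8 against 158.1) and Diras2 at least 3.41-fold (250.7 against 157.7). In the deposited normalized values the folds were 3.64 for Serpinb3a, 2.5 for Fhl2, 2.89 for Vnn3, 2.07 for Ugt3a2 and 2.19 for Scgb1b27. Downward they were 2.61 for Gdf10, 2.15 for Cldn10, 1.95 for Fam171b, 1.79 for Anxa3 and 1.74 for Diras2.

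The spread of the differences depended on the signal, with an SD of log2 differences of 0.45 in the dimmest 1679 genes detected on both arrays and 0.23 in the brightest 1679. The counts were 27 higher and 17 lower in the deposited normalized values, 28 and 19 without background correction and 65 and 47 with an offset of 50. In the main setting, 150 of the 228 genes had a signal under 400 even on their brighter array.

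**Figure D2:**
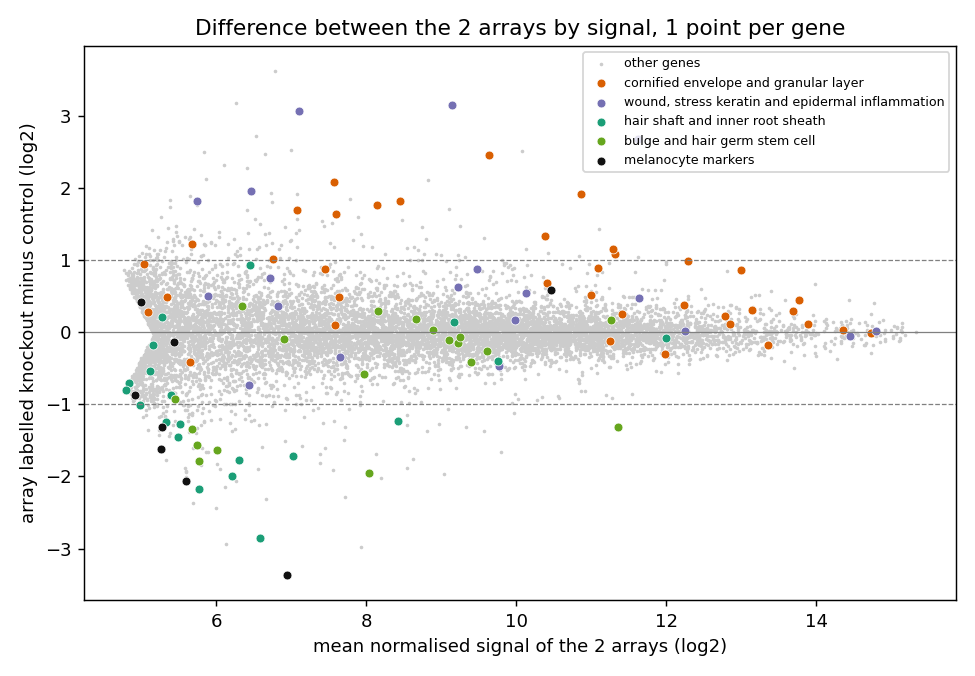
Difference between the arrays (labelled knockout minus control, log2) against the mean normalised signal (log2), with 1 point per detected gene, colours for members of 5 gene lists, and dashed lines at 2-fold. Cornified envelope members lay mostly above 0 at all signals, whereas hair shaft, bulge and melanocyte members below the lower line lay mostly at low signals.

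Genes of the granular layer and of the cornified envelope, the protein shell formed as keratinocytes die at the skin surface, were higher as a group on the array labelled knockout. Of 37 detected members, 12 were at least 2-fold higher, 0 were 2-fold lower and 25 lay between, and the median difference was 0.51 (0.48 with bounds, percentile 100). Lce1d, Lce1i, Sprr4 and Lce1f led the group with log2 differences of 2.46, 2.08, 1.91 and 1.82. Copies within the Lce1, Sprr2 and Stfa families are near-identical in sequence, so it is uncertain which copy each of these probes measured. The list members Lor, Ivl and Flg2, named after their values were seen, had differences of -0.01, -0.13 and 0.12. The epidermal lipid barrier list had a median of 0.15 (percentile 99.3) with 0 of 21 members at 2-fold, and its brightest members Elovl1 and Elovl4, which elongate fatty acids, had differences of 0.00 and -0.14.

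Genes of deeper epidermal layers had medians slightly below 0. Basal keratinocyte and hemidesmosome genes, which anchor the epidermis, had a median of -0.12 (percentile 2.1) with 0 of 15 members at 2-fold, and Krt14 and Col17a1 had differences of -0.03 and -0.15. The suprabasal list had a median of -0.08 (percentile 9.3, and 1.3 in the deposited normalized values) with 0 of 18 members at 2-fold, and Dmkn and Krt10 had -0.04 and 0.07. Krt14, Dmkn and Krt10 had control signals of 35930, 39574 and 35148, near the highest on that array (41511). Calcium handling and junction genes had a median of -0.02 (percentile 42.2, 0 of 35 at 2-fold), with -0.29 for S100a11 and 0.06 for Calm4.

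Genes of the hair shaft, the inner root sheath and the bulge were lower on the array labelled knockout, unlike those of the upper follicle. Among 20 detected genes of the hair shaft and inner root sheath, 8 were at least 2-fold lower, 0 were higher and 12 lay between, with a median of -0.94 (-0.55 with bounds, percentile 0.0). Besides Krt71, the hair keratin Krt33a was 3.98-fold lower (277.8 against 161.1), the inner root sheath keratin Krt73 was 3.43-fold lower (275.6 against 166.6) and S100a3 was at least 3.27-fold lower (245.9 against 145.0). The deposited normalized values gave smaller folds, 1.87 for Krt33a, 1.76 for Krt73 and 1.94 for S100a3. Only 9 of the 20 hair shaft and inner root sheath genes were detected on both arrays. Genes of the bulge and hair germ, where follicle stem cells reside, had a median of -0.26 (percentile 0.1), with 6 of 19 at 2-fold lower and 0 higher. This median was -0.10 over members detected on both arrays and -0.15 with no detection filter. The lower bulge genes included Tbx1, the surface marker Cd34 (3.10-fold lower, 243.5 against 160.4), the BMP antagonist Grem1 (at least 2.86-fold lower, 230.8 against 151.3) and the Wnt receptor partner Lgr5 (at least 2.60-fold lower, 221.7 against 154.2). The deposited normalized values gave 1.64-fold for Cd34, 1.7-fold for Grem1 and 1.58-fold for Lgr5. Only 4 keratin-associated protein genes were detected, with a median of -0.39 (-0.20 with bounds, percentile 11.9), 0 at 2-fold, a difference of 0.06 for Krtap16-3 and Krtap5-1 at least 1.66-fold lower (187.2 against 156.1).

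The upper follicle list was higher, with a median of 0.19 (percentile 98.6) and 0 of 11 members at 2-fold, but with bounds its median was 0.07, inside the range of -0.16 to 0.16 of the random lists. Its brightest members Krt17 and Defb6 had differences of 0.02 and 0.19. The sebaceous gland list had a median of 0.05 (percentile 70.7), with 1 of 12 members at 2-fold higher, Soat1 (at least 2.70-fold, 153.5 against 221.0), an enzyme that esterifies cholesterol. Its members Cidea and Mgst1 were 1.96-fold and 1.73-fold higher, and Elovl3 was at least 1.41-fold higher (139.3 against 175.2).

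Pigment cell markers were lower together with the hair shaft genes. Of 8 detected melanocyte markers, 2 were at least 2-fold lower and 0 higher, with a median of -1.09 (-0.50 with bounds, percentile 0.0). Besides Dct, the endothelin receptor Ednrb was at least 2.77-fold lower (227.8 against 139.5), Mlana at least 1.90-fold (196.1 against 133.5) and Pmel at least 1.73-fold (190.0 against 142.6). The deposited normalized values gave 1.88-fold for Ednrb, 1.67-fold for Mlana and 1.49-fold for Pmel. Dermal fibroblast markers had a median of -0.32 (-0.27 with bounds, percentile 0.2), with 3 of 15 at 2-fold lower and 1 higher. The lower members were Dcn (4.19-fold), Col6a1 (2.42-fold) and Serpinf1 (at least 2.02-fold), which encode matrix or secreted proteins, and the higher member was the gelatinase gene Mmp2 (2.05-fold). In the deposited normalized values the folds were 1.92 for Dcn, 1.9 for Col6a1, 1.34 for Serpinf1 and 1.96 for Mmp2.

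Genes of wounded, stressed or inflamed epidermis were higher as a group on the array labelled knockout, with a median of 0.50 (percentile 100), 5 of 19 members at 2-fold higher and 0 lower. The 5 were S100a8, Stfa3, Stfa1, S100a9 (3.90-fold, 172.6 against 294.4) and the iron-carrier binding protein gene Lcn2 (at least 2.76-fold, 152.6 against 223.2), the last named after its value was seen. The fold of S100a9 was 1.9 in the deposited normalized values. The stress keratin genes of the same list, also named after their values were seen, had differences of 0.02 for Krt16, 0.02 for Krt17 and -0.35 for Krt6b. The list for cell migration and matrix remodelling in wounds had a median of 0.03 (0.01 with bounds, percentile 66.7), with 1 of 19 members at 2-fold, the matrix gene Tnc (at least 2.74-fold lower, 226.7 against 155.2). Fscn1 and Itgb6 were 1.71-fold and 1.67-fold higher and Mmp3 was 1.42-fold lower.

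Langerhans cell and dendritic cell markers were higher on the array labelled knockout, with a median of 0.48 (percentile 100) and 2 of 13 members at 2-fold. These were H2-Ab1 (2.07-fold), part of the class II antigen-presenting complex, and Cd207 (2.0-fold), which encodes langerin, the defining lectin of Langerhans cells. H2-Eb1 and Cd74 were 1.82-fold and 1.78-fold higher. The deposited normalized values gave 1.94-fold for H2-Ab1, 1.62-fold for Cd207, 1.28-fold for H2-Eb1 and 1.71-fold for Cd74. Interferon-induced genes had a median of 0.23 (percentile 99.5), with 3 of 17 at 2-fold higher, Oasl2 (2.34-fold), Cxcl9 (2.23-fold) and Gbp2 (2.11-fold), and Mx2 at least 1.58-fold higher (156.4 against 181.5). In the deposited normalized values the folds were 1.45 for Oasl2, 1.5 for Cxcl9 and 1.75 for Gbp2. T cell markers had a median of -0.16 (percentile 15.4) with 0 of 10 at 2-fold, and differences of -0.01 for Thy1 and -0.94 for Cd3g. Macrophage, neutrophil and mast cell markers had a median of 0.45 (0.27 with bounds, percentile 95.4) with 0 of 7 at 2-fold, and differences of -0.78 for Ly6c1 and 0.75 for Lyz1.

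Markers of the remaining cell types were mostly not detected. Of 15 endothelial markers on the array 4 were detected, with a median of -0.16 (-0.03 with bounds, percentile 28.0), 0 at 2-fold, and Egfl7 at least 1.49-fold lower (181.2 against 153.3) and Vwf at least 1.12-fold higher (161.1 against 164.9). Of 21 skeletal muscle markers 5 were detected, with a median of 0.24 (0.00 with bounds, percentile 72.8), 0 at 2-fold, and differences of 0.24 for Eno3 and -0.37 for Mylpf. Of 13 adipocyte markers 5 were detected, with a median of -0.38 (-0.17 with bounds, percentile 7.3), 0 at 2-fold, a difference of 0.89 for Lpl and Cfd at least 1.42-fold lower (178.7 against 144.2). Of 4 erythroid markers 1 was detected, the haemoglobin gene Hba-a1, at -0.65. Of 10 Merkel cell markers 1 was detected, Chga, at least 1.65-fold higher on the array labelled knockout (149.6 against 184.0).

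Among signalling pathways, Wnt genes had a median of -0.16 (percentile 1.2, but 7.4 in the deposited normalized values), with 2 of 21 members at 2-fold lower, Nkd2 and Lgr5, and 0 higher. The feedback target Axin2 was 1.36-fold lower, and Tcf7 was at least 1.38-fold lower (176.9 against 150.4). Notch genes had a median of -0.31 (percentile 0.3) with 0 of 10 at 2-fold, and the targets Nrarp and Hes1 were 1.26-fold and 1.23-fold lower. BMP and TGF-beta genes had a median of -0.04 (percentile 31.1), with 1 of 17 at 2-fold, the BMP target Id1, which was 3.16-fold lower (1727 against 612.4). In the same list Bmpr1a was 1.58-fold higher, Tgfb2 was 1.5-fold lower and Nog was at least 1.17-fold lower (169.3 against 132.0). Only 3 Hedgehog genes were detected, with a median of -0.23, 0 at 2-fold, and differences of -0.23 for Smo and 0.15 for Sufu.

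The list of vitamin D metabolism and response had a median of 0.07 (percentile 76.3), with 1 of 9 detected members at 2-fold, the thrombomodulin gene Thbd, which was 2.43-fold higher (210.8 against 319.0). The calcium channel gene Trpv6 was 1.61-fold lower, and Trpv5 was at least 1.46-fold higher (143.3 against 177.2). Cyp24a1, the enzyme that inactivates the hormone and a classical VDR target, was close to background on both arrays (163.6 against 168.6, difference 0.29).

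Glycolysis and hypoxia genes were higher on the array labelled knockout, with a median of 0.21 (percentile 100) and 2 of 23 members at 2-fold, the carbonic anhydrase gene Car12 (2.44-fold) and the angiogenic factor gene Vegfa (2.27-fold). Egln3 was 1.81-fold higher, and Car9 at least 1.20-fold (149.4 against 168.0). Cholesterol synthesis genes had a median of 0.04 (percentile 78.0) over 19 detected members. Sc5d and Dhcr7 had differences of 0.69 and 0.50, and Nsdhl had -0.39. Oxidative stress and xenobiotic genes had a median of -0.05 (percentile 22.0), with 1 of 23 at 2-fold, the steroid-metabolising enzyme gene Akr1c18 (2.93-fold higher), and differences of -0.77 for Gsta1, -0.74 for Cyp1b1 and 0.67 for Mt2.

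Cell cycle genes had a median of 0.07 (percentile 81.5) with 0 of 31 at 2-fold, and differences of -0.09 for Mcm4 and 0.25 for Prc1. Immediate-early and dissociation genes, which respond to cell isolation, had a median of -0.01 (percentile 46.4) with 0 of 27 at 2-fold, and -0.12 for Zfp36 and -0.01 for Egr1. Circadian clock genes had a median of 0.11 (percentile 97.0) with 0 of 15 at 2-fold, and -0.39 for Dbp and 0.31 for Per1. Cytosolic ribosomal protein genes had a median of 0.00 (percentile 68.3) with 0 of 66 at 2-fold, and 0.00 for Rplp1 and 0.12 for Rps9. The Rplp1 probe had the highest signal on each array, so quantile normalization fixed its difference at 0.00.

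Of the 36 lists, 33 had enough detected members for a percentile, and 15 of these lay outside the central 95% of matched random lists, 7 above and 8 below, where 1.7 would do so if genes differed independently. Of the 15, the upper follicle list lay inside that range with bounds and the Wnt list in the deposited normalized values. The place of the sex-linked list depends on its mix of Xist and Y-linked genes. Percentiles were computed again only for the deposited normalized values. Under the other alternatives the place of the lists among random lists was not determined. Over the alternatives, the median nearest to 0 was less than the main value by over 1.5 times for 8 lists, at -0.10 for the bulge, -0.14 for the hair shaft, -0.06 for Wnt genes, 0.16 for wound-response genes, 0.19 for Langerhans cell markers, -0.13 for melanocyte markers, -0.16 for fibroblast markers and -0.15 for sex-linked transcripts. Lists share genes, and genes of a list vary together, so these percentiles describe the pair of arrays and do not extend to other mice.

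**Figure D3:**
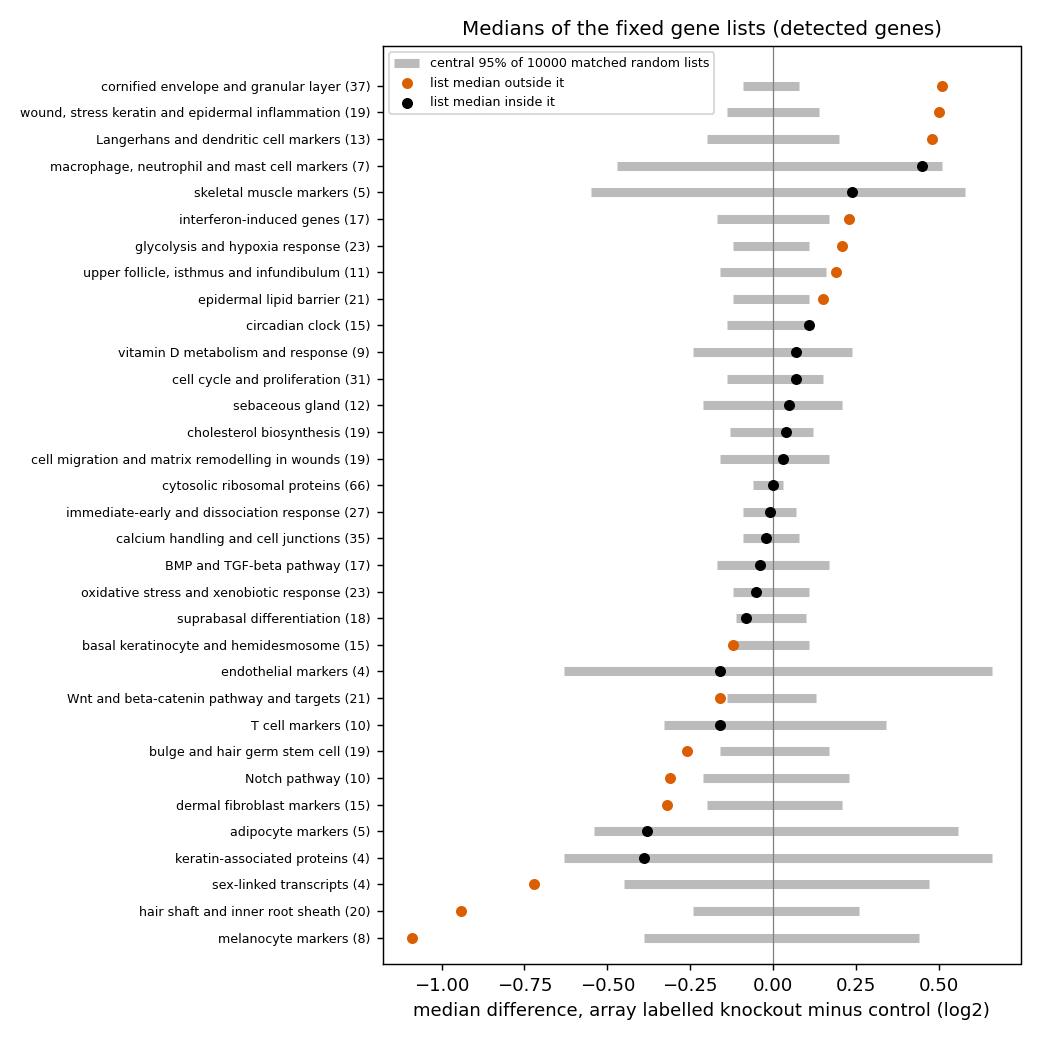
Median difference (labelled knockout minus control, log2) of each gene list with at least 4 detected members (number in brackets), as points, over grey bars for the central 95% of 10000 random lists matched on signal. Orange points, outside the bars, ran from -1.09 for melanocyte markers to 0.51 for the cornified envelope.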

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

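All alternatives reported here were planned. The number of genes at 2-fold depended most on how the background was treated. In the deposited normalized values 27 genes were at least 2-fold higher and 17 lower on the array labelled knockout, without background correction 28 and 19, and with an offset of 50 the counts were 65 and 47, all of them among the 122 and 106 of the main setting. These settings shrink differences of dim probes by construction, and of 122 named genes 77, 73 and 50 moved by more than the spread expected between probes. Thresholds of 1.5-fold and 3-fold gave 474 and 392, and 29 and 30. Median scaling, both detection filters, no filter and the mean of probes gave counts within 1.5 times of the main ones, and the difference of Vdr stayed between 0.14 and 0.39. All 15 lists outside the central 95% and all 58 named genes at 2-fold kept their sign in every setting that gave a value, although sizes differed and the sign alone does not place a list outside the random range. Over the 8 settings, the median ran from 0.36 to 0.60 for the cornified envelope list, from 0.16 to 0.50 for the wound list, from -1.26 to -0.14 for the hair shaft list, from -0.31 to -0.10 for the bulge list and from -1.62 to -0.13 for melanocyte markers. It ran from 0.19 to 0.51 for Langerhans cell markers, from -0.43 to -0.16 for fibroblast markers, from -0.20 to -0.06 for the Wnt list, from -0.33 to -0.24 for the Notch list, from -0.17 to -0.11 for the basal list and from -1.24 to -0.15 for sex-linked transcripts. It ran from 0.17 to 0.33 for interferon-induced genes, from 0.16 to 0.21 for glycolysis and hypoxia, from 0.13 to 0.20 for the upper follicle and from 0.11 to 0.15 for the lipid barrier. The endothelial list gave no value when detection on both arrays was required. Signal over background limits the dim genes, and no setting stands in for a replicate array.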

Other observations

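The tests in this part were chosen after the list results had been seen, except the test of shared probe signals, and the genes named here were chosen after their values were seen. Genes of the epidermal differentiation complex, a cluster that holds the cornified envelope genes and the S100a genes side by side, did not move as a block. In the gene order of the mouse assembly GRCm38.p6, 44 genes between S100a10 and S100a1 were detected, with a median of 0.50 (0.37 with bounds) on the array labelled knockout minus control. The 29 Lce, Sprr and other envelope genes there had a median of 0.88 (0.86 with bounds, percentile 100), with 11 at 2-fold higher and 0 lower. The 12 S100a genes had a median of -0.42 (-0.35 with bounds, percentile 0.0), and the 9 of them detected on both arrays had -0.29. Among these 9, S100a8 and S100a9 were at 3.15 and 1.96, S100a1 at -0.82 and S100a13 at -0.67. Envelope genes outside the Lce and Sprr families differed among themselves, with Lor at -0.01, Ivl at -0.13 and Flg2 at 0.12, but Hrnr at 1.08 and Rptn at 0.88. Beside the class II genes of the report, H2-Ea was 2.25-fold and the immune checkpoint ligand gene Cd274 2.57-fold higher, and Arg1, which encodes an arginase, was 3.39-fold lower.

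Hair shaft and bulge genes were lower on the array labelled knockout, mostly at dim probes: the 26 members at or below the median signal had a median of -1.13 with 12 at 2-fold lower, whereas the 13 brighter members, Vdr among them, had -0.10 (percentile 10.4) with 2 at 2-fold lower, Ccn2 (-1.31) and Krt32 (-1.24). Spread of signals near the background stays open. The percentile of 0.0 of the dim members among lists matched on signal restates the pattern on genes near the floor. The hair shaft median was -1.24 over members detected on both arrays but -0.14 with no detection filter. The 20 hair shaft and bulge members detected at p under 0.01 on both arrays had a median of -0.10 (percentile 9.6), with 4 at 2-fold lower. A lower share of growing follicles in that pool may contribute. Melanocyte markers, from a lineage outside the Krt14-expressing cells, had a median of -1.09 (-0.50 with bounds, percentile 0.0). These markers have the same limit, since only 3 of 8 were detected on both arrays and their median ran up to -0.13 over the alternatives. Dermal fibroblast markers, at -0.32, leave a lower carry-over of dermal cells open too. A different sex make-up of the pools, with an Xist difference of 1.15, cannot be told apart from genotype with 1 pool per group. Loss of VDR, which the design names, the phase of the hair cycle and the handling of each pool stay open and untested.

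Cornified envelope and wound-response genes were higher on the array labelled knockout. The basal and suprabasal lists together had a median of -0.12 against 0.51 for the cornified list, so epidermal genes were not all raised alike. This cannot decide whether there were fewer follicle cells. Basal genes such as Krt14 are also expressed in the outer cells of the follicle. The brightest suprabasal members, Dmkn and Krt10, had control signals of 39574 and 35148, near the highest on that array (41511). A signal shared among near-identical Lce, Sprr2 and Stfa copies is not the whole cause, because the 32 other members of both lists had a median of 0.34 (percentile 100). Neutrophils in the preparation would express S100a8, S100a9 and stefins, but 0 of 12 abundant neutrophil transcripts were at 2-fold higher. Of the 12, 2 were detected, Il1b and Mmp9, with differences of 0.37 and 0.31, and Ngp had signals of 141.7 against 141.5. These values gave no sign of neutrophils. They cannot exclude them, since the sensitivity of the undetected probes was not checked. A response of the epidermis to loss of VDR is a hypothesis that stays open, as do sex, the barrier state of the mice and the handling of each pool, all of them untested.

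Xist was higher and Y-linked transcripts were lower on the array labelled knockout. A larger share of male animals in the control pool is a candidate explanation, but it was read from the same 5 detected probes of Xist, Ddx3y, Kdm5d and Uty, so their directions decide nothing, and the labels used here give no sex. How far the other differences follow from sex needs arrays of separate animals.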
